A study of Mus musculus with 12 samples.

How the data were processed

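Frozen mouse heart tissue was profiled by bulk RNA sequencing in 12 libraries, 4 in each of 3 groups. The groups, taken from the titles of the samples and the design of the series, were sham operation (Sham), 30 min of ischemia with 2 h of reperfusion (I/R), and the same injury with ML264, a small molecule given to inhibit the transcription factor KLF5 (I/R + ML264). Per the labels' protocols, total RNA was extracted with TRIzol, and libraries were made with the Nextera XT kit from 1 ng of double-stranded cDNA, which does not mark strand. Paired reads of 100 bp were sequenced with at least 77 M (mega) read pairs expected per library. The labels name 2 sequencers for every library. They give no batch, sex, time of day or time at which ML264 was given, and they do not say that each library came from a separate animal, so the p-values measure the spread between these libraries.

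The authors deposited one table of estimated counts per transcript, not normalized and with replicates not pooled. Per the submitters' processing notes, FastQC and kallisto were used with the GRCm38 (mm10) genome. Their versions, the trimming and the annotation release are not given in the sources used here. The table held 104952 transcripts under 33615 gene symbols, of which 25622 had counts. Of the transcript values, 45.8% were not whole numbers, and 67 values of 1 M or more were written with 3 significant digits, which limits the precision of the most abundant mitochondrial transcripts. No pair of libraries held identical values. Between replicates, the chi-square statistic per gene was 7.76 to 75.94, above counting noise for every pair. This finds no library sequenced again from the same preparation and does not show that the libraries are separate animals.

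Transcript values were summed per gene symbol and rounded to whole numbers. Gene coordinates came from GENCODE M21 (GRCm38), which held 94.7% of the transcripts in the same version and 98.7% by accession, and 93 symbols joined transcripts of more than 1 gene. Kallisto divides reads among transcripts that share sequence. The share of 31-base words that also occur in transcripts of other genes was therefore computed. This was done for each gene named by the rule below and each mitochondrially encoded mRNA. Gm15500 and the called members of lists not called as groups were not checked in this way. Genes with more than 25% shared words are reported as uncertain.

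Total estimated counts per library were 22.26 to 29.93 M, so 3 counts, the limit a count of 0 allows, stand for 0.1002 to 0.1348 CPM (counts scaled to a library total of 1 M). Such limits and the 95% intervals on ratios of counts cover counting error only, since the reads carry no molecular identifiers. Genes were kept with the filterByExpr function at its minimum of 10 counts, which left 15952 genes and removed 9670 with some counts. The 3 comparisons were fitted in one model over all 12 libraries with edgeR 4.0.16 in R 4.3.3 (TMM factors, quasi-likelihood F-test, robust spread), and genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed. The biological coefficient of variation was 0.205. Log2 fold changes are given with their standard error (SE), and CPM values, scaled by the TMM factors, as mean ± SD.

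Before the data were examined, the groups, the tests, 39 gene lists, the rule for named genes and the alternative settings were fixed. Lists with at least 5 measured members (34 of the 39) were tested with the camera function of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera asks whether a list moved relative to all other genes. It was repeated with the correlation estimated for each list, and fry, which asks whether a list moves on balance one way, was added after the data were seen. Some genes stand in more than 1 list. For each gene, its mean log2 CPM over the 12 libraries was subtracted from its log2 CPM in each library. The mean of these values over the measured members of a list is its mean centred log2 level, in log2 units. Groups were compared on this level by exact permutation, with p not adjusted over the lists. Genes named are, per comparison, the 8 highest and 8 lowest log2 fold changes among called genes with an average log2 CPM of at least 1 and groups that do not overlap in CPM. Predicted genes, clones and pseudogenes were left out of these. Also named are up to 3 called members of each called list with the smallest adjusted p, and Klf5, Ppara, Nox4, Sptlc1 and Sptlc2. Of the genes this rule names, 1 is not reported here. Other genes are named as chosen after their values were seen. Of the named genes, 12 were picked for plotting after their values were seen.

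The alternatives were the DESeq2 1.42.0 Wald test, RLE and upper-quartile factors, no filter, a filter of 1 CPM in 4 libraries and a non-robust spread. Others were only the 2 groups compared, the replicate number as a block, limma voom with library weights, mitochondrially encoded genes left out, an absolute log2 fold change of at least 1, and each library left out in turn. Y-linked transcripts and Arntl as covariates, and the 8 libraries with Y-linked transcripts alone, were added after the data were seen. The comparisons share libraries, so covariances of fold changes and overlaps were set beside 20 simulations with no effect and beside values from libraries divided into pairs of 2.

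On simulated counts with known changes, edgeR recovered 26.5% of 1.5-fold, 63.5% of 2-fold and 90.5% of 4-fold changes for I/R against Sham over 15707 genes, with 5.7% false calls. For I/R + ML264 against I/R it recovered 21.1%, 60.3% and 90.8% over 15717 genes with 6.7% false calls, and for I/R + ML264 against Sham 24.3%, 55.9% and 91.2% over 15700 genes with 2.6%. The share of false calls by DESeq2 in the same simulations was 14.3%, 16.2% and 14.9%. Each comparison was simulated once with genes drawn independently. For I/R against Sham, 68, 63 and 63 tested genes were changed 1.5-fold, 2-fold and 4-fold. Recovery depends on how many genes change, so these shares need not hold for the real fits.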

Results

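Gene expression was measured in mouse hearts after sham operation, after 30 min of ischemia and 2 h of reperfusion (I/R), and after the same injury with the KLF5 inhibitor ML264, with 4 libraries per group. The comparison of I/R with Sham asks what the injury changed, I/R + ML264 against I/R asks what the inhibitor changed in injured hearts, and I/R + ML264 against Sham asks what still differed from uninjured hearts. Library depth was 26.09 ± 2.65 M estimated counts in Sham, 27.51 ± 2.11 M in I/R and 26.04 ± 2.09 M in I/R + ML264 (SD, n = 4). Mitochondrially encoded transcripts took 35.24% to 41.13% of the counts of a library, and the 10 most abundant genes 53.88% to 59.5%.

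The groups separated along the first dimension of a multidimensional scaling, with the 4 Sham libraries on one side, the 4 I/R libraries on the other, and 3 of the 4 I/R + ML264 libraries between them. I/R + ML264 library 2 lay among the I/R libraries on that dimension and apart from all others on the next. Within the injured groups the libraries also differed in Y-linked transcripts. Ddx3y stood at 38.79 to 51.97 CPM in all 4 Sham libraries, in I/R libraries 2 and 3 and in I/R + ML264 libraries 3 and 4, and at 0.11 to 0.48 CPM in the other 4. Arntl, a core clock gene, was at a log2 CPM of 3.39 to 3.94 in Sham libraries 2 and 3 and I/R library 1 and at 0.17 to 1.73 in the remaining 9.

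**Figure D1:**
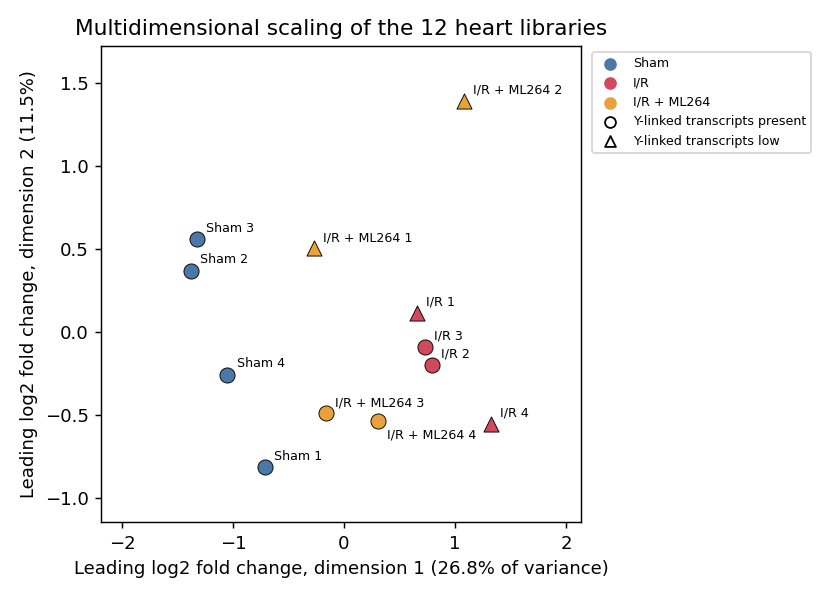
Multidimensional scaling of the 12 libraries on leading log2 fold changes, with dimension 1 (26.8% of variance) on the horizontal and dimension 2 (11.5%) on the vertical axis. Each point is a library, colours give the group, and triangles mark the 4 libraries with low Y-linked transcripts, none of which is a Sham library.

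Klf5, the gene of the inhibited factor (chromosome 14, 99298691 to 99315036, plus strand, GRCm38), was close to the limit of detection in every group. Its estimated counts per library were 3 to 10 in Sham, 2 to 15 in I/R and 3 to 9 in I/R + ML264, or 0.189 ± 0.12, 0.205 ± 0.214 and 0.235 ± 0.091 CPM (SD, n = 4), and it did not pass the filter on low counts. Kept in the fit, its log2 fold change was 0.22 ± 0.70 (SE) for I/R against Sham, 0.08 ± 0.68 for I/R + ML264 against I/R and 0.30 ± 0.69 for I/R + ML264 against Sham, with edgeR adjusted p = 0.89, 0.981 and 0.895. Among genes tied to KLF5 in the heart, Ppara, the nuclear receptor of fatty acid oxidation, had 27.1 ± 2.68 CPM in Sham, 30 ± 4.4 in I/R and 29.4 ± 1.5 in I/R + ML264, and Nox4, an NADPH oxidase, had 10.9 ± 1.09, 10.2 ± 1.03 and 10.9 ± 1.21 (SD, n = 4), with no comparison called. Sptlc1 and Sptlc2 encode subunits of serine palmitoyltransferase, the entry enzyme of sphingolipid synthesis. Sptlc2 rose in I/R against Sham (log2 fold change 0.44 ± 0.12 (SE), adjusted p = 0.0287) and was not called in I/R + ML264 against I/R (-0.42 ± 0.12, adjusted p = 0.196), while Sptlc1 was called in neither (0.14 ± 0.16 and -0.29 ± 0.16). The call of Sptlc2 ended without Sham libraries 2 or 4 or I/R libraries 2 or 4. The list of 6 measured genes linked to KLF5 had camera adjusted p = 0.545, 0.252 and 0.897 in the 3 comparisons.

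After I/R, genes of inflammatory signalling and leukocyte recruitment rose in the heart. Of 17 measured chemokines, cytokines and adhesion molecules, 10 rose and none fell in I/R against Sham (13 higher when adjusted over the list alone), with a median log2 fold change of 2.50. Il6, the cytokine interleukin 6, had 689 counts in the 4 I/R libraries and 2 in the 4 Sham libraries, a depth-scaled ratio of 327 (95% counting interval 90.1 to 2700). Cxcl2, a neutrophil chemoattractant, rose from 0.397 ± 0.509 to 13.5 ± 6.73 CPM, and the endothelial adhesion molecules E-selectin (Sele) and P-selectin (Selp) from 0.628 ± 0.154 to 12.7 ± 6.73 and from 0.218 ± 0.188 to 4.50 ± 2.97 CPM (SD, n = 4). Icam1 rose by a log2 fold change of 1.31 ± 0.23. Of 15 measured genes of the IL-6 and STAT3 pathway and the acute phase response, 8 rose (13 adjusted over the list alone), among them the signalling inhibitor Socs3 (4.62 ± 1.03), Stat3 (0.87 ± 0.15), the receptor Il6ra (0.72 ± 0.13) and Saa3 (0.78 ± 0.15, SE). Feedback genes of NF-kB rose in 8 of 13 cases (11 adjusted over the list alone), including the inhibitor Nfkbia (1.73 ± 0.33), Bcl3 (2.00 ± 0.40) and Birc3 (1.41 ± 0.18). Neutrophil markers rose in 4 of 10 cases (8 adjusted over the list alone), with Clec4e at 1.85 ± 0.43, Clec4d at 98 counts against 5 and Trem1 at 60 against 4, low counts that give ratios of 18.6 (7.7 to 58.5) and 14.2 (5.28 to 53.9). Camera adjusted p was 1.22e-13 for chemokines, 1.05e-13 for IL-6 and STAT3, 5.12e-11 for NF-kB and 7.69e-07 for neutrophil markers. With an estimated correlation the adjusted p was 0.118 for the chemokine, IL-6 and NF-kB lists and 0.281 for neutrophil markers. Markers of monocytes and macrophages (camera adjusted p = 0.978) and of T, B and NK cells (0.48) were not called. The call of Socs3 ended without any 1 Sham library or I/R library 4, and that of Clec4d without Sham libraries 1, 3 or 4. That of Trem1 ended without Sham libraries 2 or 3 or I/R library 4, and that of Clec4e without Sham library 2 or I/R library 4.

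Immediate early genes, the transcription factors and regulators induced first by stimuli, rose in 14 of 29 measured cases and fell in none (20 higher adjusted over the list alone), with a median log2 fold change of 2.22. Nr4a2, an orphan nuclear receptor, rose from 4.64 ± 1.51 to 17.1 ± 4.89 CPM (SD, n = 4), the AP-1 member Fosl2 by 2.45 ± 0.32 and Gadd45b by 2.48 ± 0.35 (SE, log2). Glucocorticoid-responsive genes rose in 6 of 13 cases (10 adjusted over the list alone, median 1.72), with the metallothioneins Mt1 (2.43 ± 0.52) and Mt2 (2.68 ± 0.51) and Klf9 (0.90 ± 0.17). Members of the KLF family rose in 5 of 12 cases (6 higher and 1 lower adjusted over the list alone), with Klf4 at 1.19 ± 0.25 and Klf7 at 0.70 ± 0.10. Mt2 shares 58.1% and Klf7 38.7% of its 31-base words with other transcripts, so both are uncertain. Camera adjusted p was 5.79e-23, 1.42e-10 and 0.000231 for the 3 lists, and adjusted p with an estimated correlation was 0.118, 0.205 and 0.281. Sham libraries were uneven in all 3 lists. The mean centred log2 level of immediate early genes was -0.21 and -2.39 in Sham libraries 1 and 2, against 0.17 to 1.18 in I/R. For glucocorticoid-responsive genes it was -0.10 and -1.95, against 0.57 to 0.75. For the KLF family it was 0.14 and -0.56, against 0.06 to 0.29, so Sham library 1 lay within the I/R range (exact permutation p = 0.0571, n = 4). The call of Mt1 ended without Sham libraries 2 or 4. The clock list was called (3 of 17 rose, Cry2 by 0.65 ± 0.13, Cry1 by 1.17 ± 0.33 and Bhlhe40 by 1.65 ± 0.38), with camera adjusted p = 0.0368 and adjusted p = 0.433 with an estimated correlation, or 0.461 with Arntl as a covariate. Its mean centred log2 level was 0.08 in Sham library 1, within the I/R range of 0.00 to 0.32. The exact permutation p was 0.0857 (n = 4). The call of this list ended without Sham libraries 2 or 3, I/R libraries 2 or 3 or I/R + ML264 library 2. The call of Bhlhe40 ended without Sham libraries 2 or 3 or I/R libraries 2 or 4, and that of Cry1 without any 1 Sham library, without I/R libraries 1, 2 or 4 or without I/R + ML264 libraries 3 or 4.

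In the integrated stress response 2 of 17 genes rose, Ppp1r15a, the phosphatase subunit that restores translation (4.63 ± 0.825 to 14.6 ± 2.61 CPM, SD, n = 4, adjusted p = 4.03e-05), and Atf4 (log2 fold change 0.56 ± 0.16). Heat shock and chaperone genes rose in 5 of 21 cases (7 adjusted over the list alone), among them Bag3 (0.46 ± 0.10) and, with 55.4% and 51.5% of their words shared, Hspb1 (0.81 ± 0.20) and Hsp90aa1 (0.61 ± 0.15). Of 21 NRF2 targets and antioxidant genes 4 rose, including heme oxygenase Hmox1 (1.66 ± 0.32) and Txnrd1 (0.85 ± 0.19). Of 19 p53 and apoptosis genes 3 rose (5 adjusted over the list alone), Cdkn1a (2.79 ± 0.60), Bcl2l1 (1.5 ± 0.38) and Tnfrsf10b (0.80 ± 0.20). Of 17 pyroptosis, necroptosis and ferroptosis genes 6 rose (6 higher and 1 lower adjusted over the list alone), with Nlrp3 (2.15 ± 0.55), the inflammasome adaptor Pycard (1.03 ± 0.25) and Ripk1 (1.20 ± 0.23). Bcl2l1 is known as an inhibitor of apoptosis and the other 2 p53 genes as an arrest gene and a death receptor. Matrix remodelling and TGF-beta genes rose in 4 of 18 cases (6 adjusted over the list alone), with Adamts9 (1.79 ± 0.32), the urokinase receptor Plaur (3.14 ± 0.66) and Tgfb2 (0.67 ± 0.12). Mitochondrially encoded mRNAs rose in 2 of 13 cases (3 adjusted over the list alone), mt-Nd1 by 0.51 ± 0.09 and mt-Nd2 by 0.36 ± 0.09. Of 81 ribosomal protein genes Rpl37a rose (0.65 ± 0.18) and Rpl29 fell (-0.66 ± 0.16). Both are uncertain with 28.5% and 44.9% of their words shared, and neither passed when adjusted over the list alone. Camera adjusted p was 0.0363 for the integrated stress response, 0.000146 for heat shock, 0.0262 for NRF2 and 0.0236 for p53. It was 0.00832 for pyroptosis, 0.00113 for matrix, 0.0236 for mitochondrial mRNAs and 0.0368 for ribosomal proteins. In the same order over these 8 lists, adjusted p with an estimated correlation was 0.418, 0.438, 0.438, 0.274, 0.438, 0.281, 0.596 and 0.596. In mean centred log2 level the groups overlapped for 5 of the 8 lists, ribosomal proteins among them. Heat shock genes were at 0.12 and 0.05 in Sham libraries 1 and 4, within the I/R range of 0.05 to 0.47 (exact permutation p = 0.0857), and the integrated stress response at 0.01 in Sham library 1 and -0.19 in I/R library 4 (exact permutation p = 0.229). Pyroptosis genes were at 0.03 in Sham library 3 and -0.05 in I/R library 1 (exact permutation p = 0.0571), and mitochondrial mRNAs at 0.19 in Sham library 2 and 0.07 in I/R library 3 (exact permutation p = 0.143, n = 4 in each). The list call ended without Sham libraries 2 or 3 or I/R libraries 2 or 3 for the integrated stress response, and without Sham library 2 or I/R library 4 for NRF2. It ended without Sham libraries 1 or 3 or I/R library 4 for mitochondrial mRNAs, and without Sham library 1 or I/R libraries 3 or 4 for ribosomal proteins. With Arntl as a covariate the camera adjusted p was 0.0666 for the integrated stress response, pyroptosis and ribosomal lists, 0.0714 for mitochondrial mRNAs, 0.0938 for p53 and 0.105 for NRF2. With Y-linked transcripts as a covariate it was 0.115 for NRF2 and 0.14 for ribosomal proteins. Leaving out 1 library also ended calls of single genes. Those of Bag3, Hspb1 and Plaur ended without Sham libraries 2 or 3, the last 2 also without I/R library 4, and that of Txnrd1 without Sham libraries 1, 2 or 4. The calls of Cdkn1a (Sham 2, 3 and 4, I/R 1 and 4), Tnfrsf10b (Sham 2 and 3, I/R 2, 3 and 4), Nlrp3 (Sham 1, 2 and 4, I/R 3 and 4), Hsp90aa1 (Sham 2, 3 and 4, I/R 2 and 3) and mt-Nd2 (Sham 1, 3 and 4, I/R 1 and 4) each ended without any 1 of the libraries in brackets. So did those of Atf4 (Sham 2 and 3, I/R 1 to 4), Bcl2l1 (Sham 1 to 4, I/R 1 to 3), Pycard (Sham 1 to 4, I/R 1, 2 and 4), Rpl37a (Sham 1, 3 and 4, I/R 1, 3 and 4) and Rpl29 (Sham 3, I/R 1 and 4).

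Other than neutrophil markers, no tested list of cell-type markers was called in I/R against Sham by camera in the fit of all 12 libraries. Cardiomyocyte markers had a median log2 fold change of 0.07 over 18 genes (1 rose, adjusted p = 0.547), fibroblast markers 0.04 over 12 (none called, 0.978), endothelial markers 0.00 with a mean of -0.03 over 14 (2 rose and 2 fell, 0.858). Smooth muscle and pericyte markers had a median of -0.01 over 10 (1 fell, 0.48). Platelet markers had 2.01 over 6 (none called, 0.0563). By camera the platelet list was called in 5 of the 12 fits that left out 1 library. Its mean centred log2 level was 3.09 in I/R library 4 and -0.49 to 1.00 in the other I/R libraries. Erythroid markers had 0.10 over 6 with a test direction of lower (none called, 0.978). Monocyte and macrophage markers had a median of -0.05 but a mean of 0.16 and a test direction of higher (1 rose and 1 fell of 14). PPAR targets and fatty acid oxidation genes had a median of 0.00 over 32 (3 rose and 1 fell, 0.858), and nuclear-encoded respiratory chain genes a median of 0.01, a mean of -0.01 and a test direction of lower over 50 (none called, 0.978). Ceramide and sphingolipid genes had a median of 0.06 over 26 (3 rose and 2 fell, 0.478) and NADPH oxidase subunits -0.09 over 7 (none called, 0.978). Hypoxia and glycolysis genes (median 0.07, 3 of 24 rose, 0.119), cardiac stress and fetal genes (0.18, 1 of 16, 0.129), calcium handling and ion channel genes (0.04, 1 of 25, 0.978), interferon-stimulated genes (0.19, 1 of 22, 0.978) and proliferation genes (0.00, 1 of 16, 0.978) were not called either. In mean centred log2 level, hypoxia and glycolysis genes still did not overlap between the groups (0.02 to 0.06 in I/R, -0.15 to -0.01 in Sham). Nor did T, B and NK cell markers (-0.36 to -0.03 in I/R, -0.01 to 0.12 in Sham). The exact permutation p was 0.0286 for each (n = 4), not adjusted over the lists. Atrial, adipocyte, skeletal muscle, epicardial and lung epithelial markers had fewer than 5 measured members and were not tested.

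Across all genes, 1235 of 15952 changed in I/R against Sham, 730 higher and 505 lower, of which 401 changed at least 2-fold (295 higher and 106 lower). With upper-quartile factors the division was 620 higher and 676 lower. The largest rises that met the rule for named genes were Il6, Tpm3-rs7, Kcnj14, Sytl1, Cxcl2, Socs3, Sele and Selp. Of these, Tpm3-rs7 (563 counts against 4) and Kcnj14 (568 against 9) share 78.6% and 35.6% of their words with other transcripts, Tpm3-rs7 mainly with Tpm3, and are uncertain, and Sytl1, a protein of vesicle traffic, had 1408 counts against 34. Among the 8 largest falls by the same rule were Atp8b5 (-2.35 ± 0.29), the apelin receptor Aplnr (-2.27 ± 0.56), Fam84b (-1.87 ± 0.22), Cyth4 (-1.71 ± 0.32), Klhdc8a (-1.50 ± 0.26), Olfr974 (-1.49 ± 0.32) and Tnfrsf19 (-1.46 ± 0.33), of which Fam84b shares 41.1% of its words. The fit without Sham library 2, 3 or 4 or without I/R library 4 called 738, 659, 702 and 694 genes, and the fits with Y-linked transcripts or Arntl as a covariate 446 and 636, or 57 with both. Of the 58 named calls, 33 stayed in all 12 fits that left out 1 library. Aplnr, Bcl2l1, Cry1, Kcnj14, Pycard and Tpm3-rs7 were lost in 7 to 9 of them. The replicate number as a block ended 11 of the 58 and the fit with no filter 8.

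**Figure D2:**
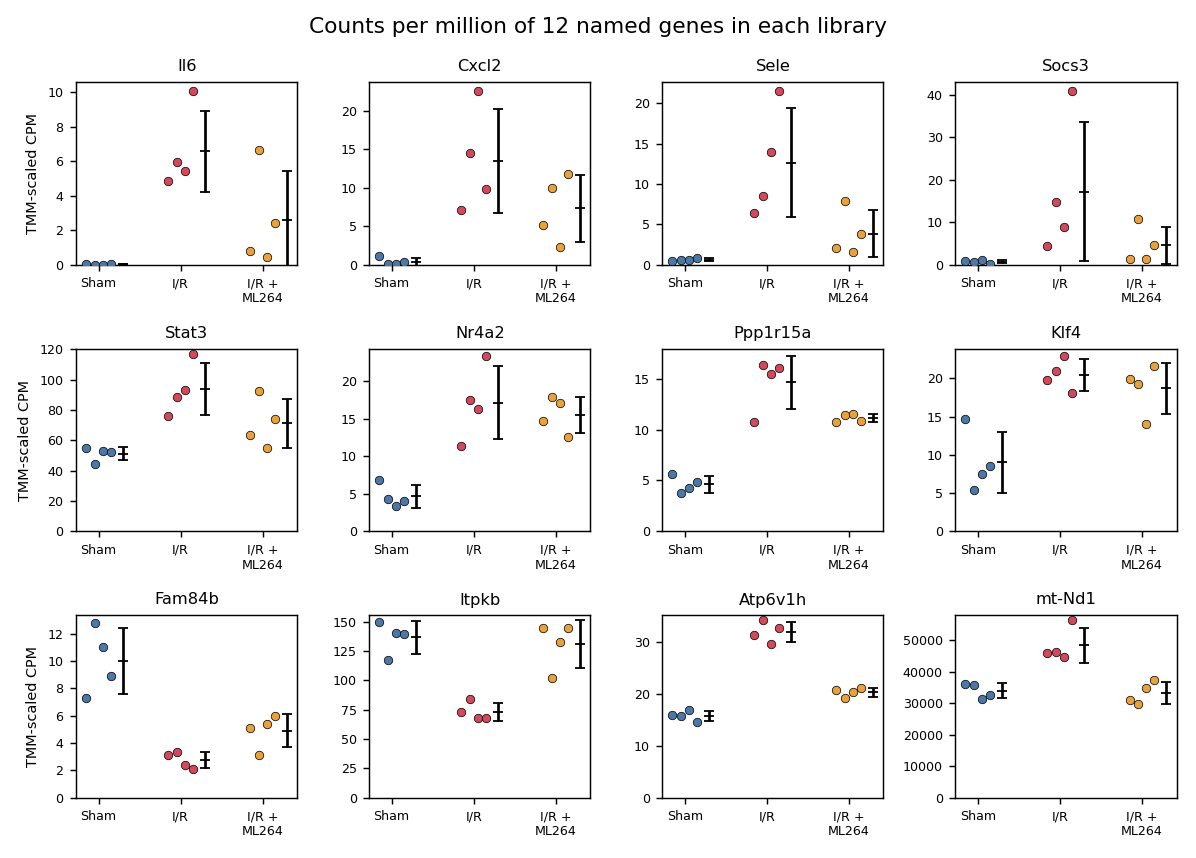
CPM (vertical axes, linear and starting at 0) of 12 named genes in each of the 12 libraries by group, with points for libraries and bars for mean ± SD (n = 4, lower arms cut at 0). Il6 stood at 6.59 ± 2.36 CPM in I/R and 0.0201 ± 0.0236 in Sham, and Itpkb at 73.2 ± 7.88 in I/R and 131.0 ± 20.2 in I/R + ML264.

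In injured hearts given ML264, 8 genes differed from untreated I/R hearts, 2 higher and 6 lower, and all 8 had changed in the opposite direction in I/R against Sham. Itpkb, an inositol trisphosphate kinase, rose from 73.2 ± 7.88 to 131.0 ± 20.2 CPM (Sham 136.7 ± 13.78), and Atp6v1h, a subunit of the vacuolar proton pump, fell from 32.0 ± 1.97 to 20.4 ± 0.882 CPM (Sham 15.86 ± 0.9688, SD, n = 4), each with adjusted p = 0.0091. The pseudogene Gm15500, named because it completes the 8 and chosen after its values were seen, rose by a log2 fold change of 0.66 ± 0.099. The RNA-binding proteins Ilf2 and Rbm25 fell (-0.50 ± 0.08 and -0.40 ± 0.07), as did Nexn, a protein of the cardiac Z-disc (-0.50 ± 0.08), and mt-Nd1 and mt-Nd2, which encode subunits of respiratory complex I (-0.54 ± 0.09 and -0.57 ± 0.09, SE). By edgeR no called gene changed at least 2-fold, and DESeq2 called 153 genes. By edgeR 1660 genes had an unadjusted p under 0.05, where 798 would on average with no effect. Genes can vary together between libraries, so this count can stray far from that average, and its excess was not tested. The call of Atp6v1h was lost without I/R + ML264 library 1. That of Itpkb was lost without that library or I/R library 1 or 4. Those of the other 5 named genes were lost in 7 to 10 of the 12 fits that left out 1 library. With the replicate number as a block all 7 named calls ended, with a non-robust spread 5 and with only the 2 groups 4. With DESeq2 or limma voom none ended. Without I/R + ML264 library 1 no gene was called, and without I/R + ML264 library 2 there were 85. Without Sham libraries 2 or 4 or I/R library 2 there were 3, without I/R libraries 1 or 4 there were 2 and without I/R library 3 there were 5. Among the 8 libraries with Y-linked transcripts 2 genes were called, neither among the 8. Of the 35 splits of the I/R and I/R + ML264 libraries, 2 gave at least 8 genes, the real one included.

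As groups, 8 lists were lower in I/R + ML264 than in I/R by camera at the preset correlation, and none with an estimated correlation. The mitochondrially encoded mRNAs had 2 of 13 members called lower (8 adjusted over the list alone), a median log2 fold change of -0.40 and camera adjusted p = 2.19e-13. Of the 13 members, mt-Nd3, mt-Nd4, mt-Nd4l, mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 share 62.8% to 100% of their words with other transcripts and are uncertain. Leaving out 1 library did not end the call of this list. In the other 7 lists no member was called by edgeR over all genes. These were IL-6 and STAT3 genes (median -0.56, 2 of 15 lower adjusted over the list alone, camera adjusted p = 2.3e-07), NF-kB feedback genes (-0.47, 3 of 13, 2.32e-05), heat shock genes (-0.27, 0 of 21, 2.32e-05) and chemokines, cytokines and adhesion molecules (-0.51, 0 of 17, 0.00382). The others were pyroptosis, necroptosis and ferroptosis genes (-0.15, 0 of 17, 0.00706), immediate early genes (-0.39, 1 of 29, 0.00754) and matrix genes (-0.10, 0 of 18, 0.0395). With an estimated correlation the adjusted p was 0.283 for mitochondrial mRNAs and for IL-6 and STAT3 genes, 0.49 for NF-kB, 0.826 for immediate early genes and 0.631 for the other 4. In mean centred log2 level, the mitochondrial mRNAs were at -0.30 to -0.11 in I/R + ML264 and 0.07 to 0.40 in I/R. The exact permutation p was 0.0286, the smallest that 4 against 4 can give. In the other 7 lists the 2 groups overlapped. Chemokines were at 0.19, 1.14, -0.17 and 0.47 in I/R + ML264 libraries 1 to 4 against 0.07 to 1.49 in I/R, with an exact permutation p = 0.257, as for immediate early genes, and for pyroptosis genes it was 0.229 (n = 4). Neutrophil markers (median -0.51, camera adjusted p = 0.0885), the KLF family (-0.10, 0.252) and glucocorticoid-responsive genes (-0.17, 0.169) were not called. Cardiac stress and fetal genes (-0.27, 0.0885) and proliferation genes (-0.15, 0.0525) were not called either. In mean centred log2 level, cardiac stress genes were at -0.14 to -0.06 in I/R + ML264 and 0.01 to 0.35 in I/R. They thus did not overlap (exact permutation p = 0.0286, n = 4). The call of immediate early genes ended without I/R libraries 2 or 4 or I/R + ML264 library 3, and that of chemokines without I/R libraries 3 or 4 or I/R + ML264 library 3. That of pyroptosis genes ended without I/R library 4 or I/R + ML264 library 3, and that of matrix genes without I/R libraries 2, 3 or 4 or I/R + ML264 library 3. Without I/R library 1 camera called 13 lists, and without I/R + ML264 library 3 it called 4.

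The genes changed by I/R lay closer to Sham in I/R + ML264. For the 730 genes higher in I/R, the median log2 fold change was 0.84 in I/R and 0.49 in I/R + ML264, both against Sham, and -0.34 between the treated and untreated injured groups. For the 505 lower genes the medians were -0.70, -0.33 and 0.36. Because these genes were chosen on the same I/R libraries, part of this shift arises with no effect. Of the genes called in both comparisons, 6 were higher in I/R and lower with ML264, where independent lists would share 0.275, and 2 went the other way, where they would share 0.0633. None of 20 simulations with no effect gave such a gene. These simulations hold no change in any group, I/R included, so few genes are called and an absent overlap is near certain. They cannot show how many shared genes arise by chance when I/R changes genes and ML264 does not. Nor do they carry differences between libraries such as those in Y-linked transcripts. The split of the I/R and I/R + ML264 libraries by Y-linked transcripts gave 13 genes called in opposite directions in 1 orientation and 1 in the other. Of the 14 genes called between its sets, 5 are Xist or Y-linked genes and 9 are not. All Sham libraries hold Y-linked transcripts, so Y-linked genes can move back in this split by the choice of libraries alone. Over all genes, which are not independent replicates, the covariance of the 2 sets of fold changes was -0.133 (r = -0.588) against -0.0518 (r = -0.50) simulated with no effect, a difference of -0.0815. With the I/R libraries divided into pairs that shared none between the comparisons, the mean covariance was -0.0822, between -0.098 and -0.0693.

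Compared with Sham, hearts with I/R and ML264 had 46 changed genes, 41 higher and 5 lower, 26 of them at least 2-fold. Gem, a small GTPase that regulates calcium channels, rose from 1.31 ± 0.514 to 5.50 ± 1.75 CPM, Nr4a2 from 4.64 ± 1.51 to 15.5 ± 2.41 and Ppp1r15a from 4.63 ± 0.825 to 11.1 ± 0.417 CPM (SD, n = 4). Cytip, Gfpt2, Cd83, Slc16a11, Myo7b and Eid3 rose by log2 fold changes of 1.68 to 1.96, and Cry2 by 0.67 ± 0.13. Lower genes were Mlst8 (-1.39 ± 0.24), the transferrin receptor Tfrc (-1.26 ± 0.21), Fam84b (-1.04 ± 0.21) and Zfp90 (-0.73 ± 0.14, SE), of which Fam84b and Zfp90 share 41.1% and 77.9% of their words and are uncertain. The higher genes included 38 that were also higher in I/R against Sham, where independent lists would share 1.88, and the lower genes included 4, where they would share 0.158. Simulations with no effect gave 0.05 on average in either direction, but they hold no change in any group, so few genes are called and a low overlap is near certain. The covariance of the 2 sets of fold changes was 0.211 (r = 0.755) against 0.0513 (r = 0.497) simulated, and 0.173 on average with the Sham libraries divided. Of the 14 named calls, those of Gem and Ppp1r15a stayed in all 12 fits that left out 1 library. With Y-linked transcripts, Arntl or both as covariates edgeR called 15, 12 and 0 genes, and 11, 10 and 14 of the 14 named calls ended. All 14 kept their direction in these fits. The fits called 77, 12, 9 and 9 genes without Sham libraries 1 to 4, and 101, 15, 96 and 11 without I/R + ML264 libraries 1 to 4.

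Against Sham, 12 lists were higher and 1 was lower in I/R + ML264 by camera. Immediate early genes had 1 of 29 members called (15 adjusted over the list alone), a median log2 fold change of 1.62 and camera adjusted p = 7.56e-27. Chemokines, cytokines and adhesion molecules had 0 of 17 (11 adjusted over the list alone, median 1.97, 2.39e-13) and glucocorticoid-responsive genes 0 of 13 (8, 1.45, 2.3e-12). In the same terms, IL-6 and STAT3 genes had 0 of 15 (6, 0.51, 8.62e-07), neutrophil markers 0 of 10 (7, 2.38, 1.9e-06) and NF-kB feedback genes 0 of 13 (5, 0.66, 5.54e-06). Adjusted p with an estimated correlation was 0.201 for the first 2 of these, 0.22 for the next 2 and 0.278 for the last 2. I/R + ML264 libraries were uneven in several of these lists. In mean centred log2 level, glucocorticoid-responsive genes were at -0.04, 0.93, 0.02 and 0.65 in libraries 1 to 4, against -0.10 in Sham library 1. Chemokines were at 0.19, 1.14, -0.17 and 0.47, against -1.77 to -1.09 in Sham. In the last 2 lists some libraries lay near or within Sham. The mean centred log2 level of neutrophil markers was -0.86 and -0.91 in libraries 1 and 3, near the -1.40 to -0.97 of Sham. In libraries 2 and 4 it was 1.52 and 1.16. The level of NF-kB genes was -0.51 in library 3, within the Sham range of -0.69 to -0.45. Also called higher were the KLF family (0 of 12 members called, 4 higher and 1 lower adjusted over the list alone, median 0.26, camera adjusted p = 0.000422), the integrated stress response (1 of 17, 2 higher, 0.13, 0.00497) and the clock list (1 of 17, 1 higher, 0.37, 0.0139). NRF2 targets (0 of 21, none, 0.11, 0.0183), matrix genes (0 of 18, 4 higher, 0.10, 0.0367) and ribosomal proteins (0 of 81, none, 0.13, 0.0367) followed. For these 6 lists the adjusted p was 0.278, 0.278, 0.278, 0.396, 0.428 and 0.705 with an estimated correlation. By mean centred log2 level, the exact permutation p was 0.0857 for the KLF family, matrix genes and mitochondrial mRNAs. It was 0.0571 for the clock list and 0.286 for ribosomal proteins (n = 4). The matrix call ended without Sham library 2 or I/R + ML264 libraries 1, 2 or 4, the ribosomal call without Sham library 1 or I/R + ML264 libraries 1, 2 or 3, the NRF2 call without Sham library 2 and the clock call without Sham libraries 2 or 3. With Y-linked transcripts as a covariate the camera adjusted p was 0.186 for NRF2, 0.14 for matrix genes and 0.213 for ribosomal proteins, and with Arntl it was 0.182, 0.0928 and 0.0892, and 0.515 for the clock list. Mitochondrially encoded mRNAs were lower (median -0.15, 0 of 13 called, 3 adjusted over the list alone, camera adjusted p = 0.000973), with adjusted p = 0.396 with an estimated correlation. Heat shock genes (0.345), p53 genes (0.146) and pyroptosis genes (0.378) were not called.

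**Figure D3:**
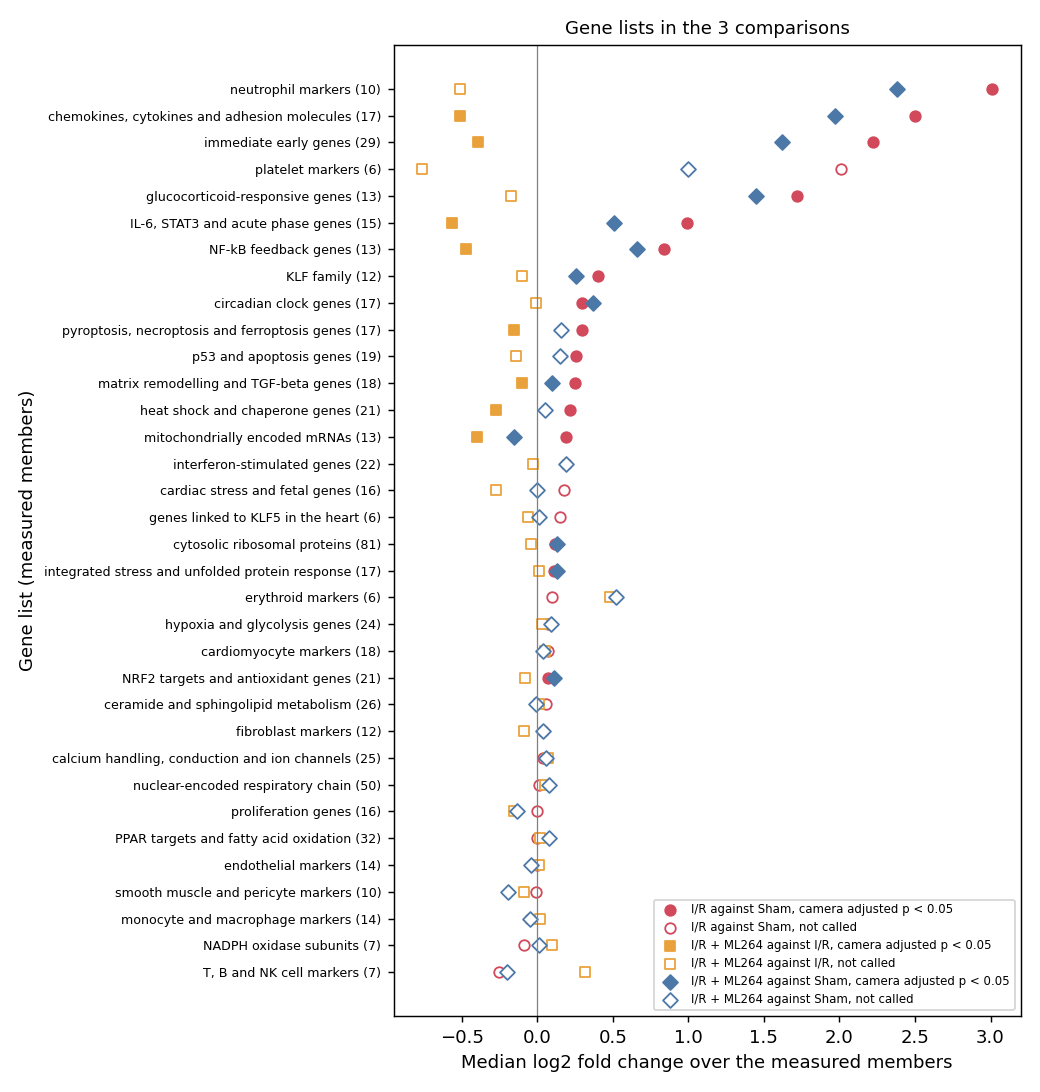
Median log2 fold change (horizontal axis) of the measured members of the 34 tested gene lists (vertical axis, members in brackets) in the 3 comparisons, with filled symbols for lists called by camera at the preset correlation. Chemokines, cytokines and adhesion molecules had medians of 2.50 in I/R against Sham, 1.97 in I/R + ML264 against Sham and -0.51 in I/R + ML264 against I/R, and no list was called with an estimated correlation.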

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

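The tests of the genes moved back and of the covariance over other splits, of I/R libraries divided into pairs, of cardiomyocyte markers, of the word shares of mt-Nd1 and mt-Nd2, of Y-linked transcripts and Arntl, and by fry were chosen only after the result was seen.

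In 20 of 252 groups of 4 values, 1 library lay far from the other 3, where chance gives about 13, and 7 of the 20 were in I/R library 1. That library had less Ppp1r15a (10.8 CPM, others 15.5 to 16.3) and Tnfrsf10b (13.3, others 17.1 to 17.8) and more Saa3 (50.7, others 33.0 to 34.5) and Myo7b (9.26, others 4.16 to 4.75). It had 15 counts of Klf5 against 2 to 3, and Gm20594 took 10.5% of its counts (others 13.7 to 13.9) and Grip2 3.2% (others 1.4 to 1.66). In I/R library 4, mt-Nd1 was at 56531 CPM (others 44647 to 46392) and Mt1 at 14.7 (others 5.68 to 7.04). Among Sham libraries, Aplnr was at 57.1 CPM in library 3 (others 32.4 to 35.9), Clec4d at 0.181 in library 2 (0 in the others), Eid3 at 1.16 in library 4 (others 0.86 to 0.869) and Nfkbia at 3.21 in library 1 (others 1.59 to 1.77). Klf5 had 10 counts in Sham library 2 (others 3 to 4), and Grip2 took 1.54% of counts in Sham library 1 (others 1.3 to 1.34). With ML264, library 2 held 21893 genes with a count (others 19285 to 19551) and Eid3 at 4.68 CPM (others 2.34 to 2.56). Ilf2 was at 36.0 in library 1 of that group (others 42.9 to 43.3), and in library 3 Kcnj14 was at 5.84 (others 0.0355 to 0.309) and Sptlc1 at 6.74 (others 5.46 to 5.64).

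Other splits of the 8 libraries of each comparison, 35 in number with the real one, were tested in the same way. For I/R against Sham, only the real split gave as many genes (1 of 35, real 1235, highest other 0). The same held for the lists called by fry (1 of 35, real 11, highest other 1). Both argue against chance, but 1 of 35 is the smallest share possible and was not adjusted over the measures tested. The other splits mix the groups, which can widen the spread and lower their counts. For lists called by camera chance is not excluded (4 of 35, real 16, highest other 17). The other splits with as many lists divide the groups unevenly, so they hold part of the I/R difference and cannot decide this. For I/R + ML264 against I/R, chance cannot be excluded for the genes (2 of 35, real 8, highest other 14). Nor can it for the lists by camera (16 of 35, real 8, highest other 17) or by fry (real 1, highest other 2). The split with 14 genes is the one by Y-linked transcripts, and 5 of the 14 are Xist or Y-linked genes. With Y-linked transcripts as a covariate 9 genes were called. For I/R + ML264 against Sham, the splits argue against chance for the genes with the same limits (1 of 35, real 46, highest other 6). They do not for the lists by camera (7 of 35, real 13, highest other 19) or by fry (real 1, highest other 1). The 46 genes fell to 15 with Y-linked transcripts, 12 with Arntl and 0 with both as covariates. Differences between libraries other than the groups are thus not excluded for them.

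Fold changes in I/R + ML264 against I/R ran opposite to those in I/R against Sham, and the 8 genes called in the former had all changed the other way. The 2 comparisons share the I/R libraries, which alone brings a negative covariance, yet with those libraries divided the covariance remained below 0 in all 6 pairs (-0.0693 at the highest), which argues against sharing as the whole cause. With Y-linked transcripts or Arntl as a covariate, the difference from simulation was 0.95 and 0.91 of that without, which argues against either as the whole cause. Chance was not excluded by the splits. A covariance as far below 0 came from 4 of 35 (real -0.133, lowest other -0.149), and 2 of 35 moved as many genes back (real 8, highest other 13). The other splits with such a covariance each exchange only I/R + ML264 library 2 with an I/R library. They thus hold most of the real grouping and cannot decide this for the covariance. Each split entered by its stronger orientation, a choice made after the values were seen, and counting orientations apart gives 4 and 2 of 70. For the genes moved back the share is 0.0571 of splits or 0.0286 of orientations, so that result depends on this choice. The only other split as large is the one by Y-linked transcripts. All Sham libraries hold these, so Y-linked genes can move back in that split by the choice of libraries alone. Of the 14 genes it called, 5 are Xist or Y-linked genes and 9 are not. An effect of ML264 may underlie the pattern and is not separated from chance by the splits.

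Fewer genes were called in I/R against Sham with Y-linked transcripts (446) or Arntl (636) as a covariate. The median absolute log2 fold change of the 1235 genes went from 0.76 to 0.70 and 0.75 and the median SE from 0.17 to 0.19 in both fits, all genes kept their direction, and 432 and 561 of them were still called. With both covariates 57 genes were called, 56 of them among the 1235, at a median of 0.63 with an SE of 0.23, and 54 of the 58 named calls ended. In the libraries with Y-linked transcripts, and in those with low Arntl, fold changes were 0.95 of those in all libraries at the median (quartile values 0.84 to 1.05 and 0.82 to 1.09), which argues against either alone as the whole cause of the changes. The 2 together were not tested in this way. These genes were called on the same libraries, so the ratios lie near 1 partly by construction, and the fit on libraries with Y-linked transcripts alone called 553 genes, 482 of them among the 1235. Arntl could itself respond to the injury. The labels give no sex, but Y-linked transcripts were low, as in female hearts, in 2 of the I/R libraries and in no Sham library. Sex is thus likely confounded in part with the injury, and time of day is not given. The part of sex and of time of day in single genes stays open beside that of the injury.

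Mitochondrially encoded mRNAs were lower in I/R + ML264 than in I/R, with a median of -0.40. A lower share of cardiomyocyte RNA would lower the cardiomyocyte markers as much, and these had a median of 0.05 (quartile values -0.05 to 0.10), which argues against it. For mt-Nd1, 0% of 31-base words occur in other GENCODE M21 transcripts, which argues against reads shared with annotated transcripts. Copies outside that annotation were not searched. Shared reads stay open for mt-Nd2 with 13.5%. This test was first set for both genes together, met neither bound, and was divided after its result was seen. For the list, the sum of the 13 mRNAs and 3 of their nuclear copies changed by -0.20 ± 0.10 (SE, n = 4, exact p = 0.143), and the 13 mRNAs alone by the same. The 3 copies alone changed by -0.49 ± 0.82 (exact p = 0.714), which shows no gain but is too wide to exclude one, so a shift of reads between them and a fall in the mRNAs cannot be told apart, and other nuclear copies were not included. The list itself did not overlap between the groups in mean centred log2 level (exact p = 0.0286, the smallest possible, not adjusted over the lists). It was called by fry (adjusted p = 0.0463), but other splits of these libraries also called lists by fry (real 1, highest other 2). Neither result separates a shift of reads from a fall in the mRNAs. An effect of ML264 on these mRNAs may be a candidate explanation and was not tested apart from these.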

How the results depend on the processing

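The covariate fits, the fit on libraries with Y-linked transcripts and fry are tests chosen only after the data were seen. No call of a gene named by the rule reversed its direction under the alternatives run for it. Against 1235 genes in I/R against Sham, an absolute log2 fold change of at least 1 left 401, Y-linked transcripts as a covariate 446, libraries with Y-linked transcripts 553, Arntl 636 and both covariates 57. Leaving out 1 library gave 659 (without Sham library 3) to 1485. Against 8 genes in I/R + ML264 against I/R, these were 0 at a log2 fold change of 1 (by edgeR), DESeq2 153 (all 8 among them), no filter 26, non-robust spread 2, the replicate block 1, libraries with Y-linked transcripts 2 and both covariates 26. They were 0 (without I/R + ML264 library 1) to 85 (without library 2 of that group) with 1 library left out. Against 46 genes in I/R + ML264 against Sham, they were 26 at a log2 fold change of 1, DESeq2 370, no filter 77, non-robust spread 72, only the 2 groups 27, the block 19, Y-linked transcripts 15, libraries with Y-linked transcripts 27, Arntl 12 and both 0. With 1 library left out they were 9 to 101. Of the 8 genes moved back, 0 were left at a log2 fold change of 1, and there were 112 by DESeq2, 23 with no filter, 2 with a non-robust spread, 1 with the block, 2 in libraries with Y-linked transcripts. There were 0 to 79 with 1 library left out. The covariance was -0.625 over called genes and -0.0822 with I/R libraries divided, and -0.19 to -0.132 with 1 library left out. Lists called were 0, 0 and 0 with an estimated correlation and 11, 1 and 1 by fry in the 3 comparisons, 9 with Arntl for I/R against Sham, and 13 to 17, 4 to 13 and 10 to 16 with 1 library left out. Of the 27 alternatives, 18, 12 and 9 kept the count of genes within 1.5 times in the 3 comparisons. For named genes, 1304 of 1581, 212 of 284 and 336 of 468 values kept their side of the threshold. A change of sign was counted only where either fit called the gene, and none occurred there. For pairing, the mean of its group was subtracted from the log2 CPM of each gene. These deviations correlated across genes at -0.111 to 0.097 (median 0.002) between same-number libraries of different groups. Other pairs had a median of -0.013 and a highest value of 0.142, so the number was not used as pairing outside the block fit. The log2 fold change of Klf5 ran from -0.82 to 0.76, -0.18 to 1.11 and 0.09 to 0.84 with 1 library left out and was never called. The cause of these differences was not tested, apart from the fewer libraries or genes some settings hold. At the depth here, genes with fewer than 10 counts in most libraries, Klf5 among them, were too low to pass the filter.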

Other observations

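The fit of Y-linked transcripts with treatment is a test chosen only after the result was seen. Called members of lists that were not called as groups were also chosen after their values were seen.

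In I/R against Sham, the endothelial genes Esam (log2 fold change 0.72 ± 0.14) and Flt1 (0.60 ± 0.15) rose and the receptors Tek (-0.45 ± 0.11) and Kdr (-0.78 ± 0.19) fell (SE, n = 4). The macrophage genes Cd14 rose (2.93 ± 0.49) and Adgre1 fell (-0.68 ± 0.16). In sphingolipid metabolism Sphk1 (2.10 ± 0.34) and Sgms1 (0.86 ± 0.15) rose, and Cers4 (-0.51 ± 0.13) and Asah1 (-0.45 ± 0.10) fell. Ppargc1a (1.47 ± 0.34) and Pdk4 (0.83 ± 0.22), regulators of oxidative metabolism, and Lpl (0.23 ± 0.06) rose, and Slc25a20, the carnitine carrier, fell (-0.32 ± 0.09). The glycolysis regulator Pfkfb3 (1.32 ± 0.29) and the potassium channel Kcna5 (1.45 ± 0.29) rose.

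Sham libraries 2 and 3 had mean centred log2 levels of -2.39 and -1.86 for immediate early genes and -1.95 and -1.63 for glucocorticoid-responsive genes. Their levels for clock genes were -0.55 and -0.62. In the same order of lists, Sham libraries 1 and 4 had -0.21 and -0.95, -0.10 and -0.52, and 0.08 and 0.00.

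Whether the effect of ML264 differed with Y-linked transcripts was tested over the 8 injured libraries, and edgeR called 1 of 15452 genes, Gdpd3, with 566 genes at an unadjusted p under 0.05 where 773 would by chance.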
